A study of Danio rerio with 2 samples.

How the data were processed

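Heart ventricles of homozygous sulf1 mutant zebrafish (allele sjr9, AB strain, 3 months old) were dissociated with collagenase and TrypLE, and per the labels 14000 cells of each suspension were loaded for 10x Genomics 3' v3.1 single-cell libraries. There were 2 libraries, 1 of uninjured ventricles (a pool of 4) and 1 of ventricles taken 4 days after cryoinjury, for which the number of animals is not clear from the labels. Both carried the same batch label.

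The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 8.0.1 per the file headers and not filtered for cells. The labels list Cell Ranger 6.1.2, Seurat and the genome build GRCz11 without saying which step each served, and the annotation behind the gene identifiers is not given in the sources used here. Each matrix had 36351 features with 36109 symbols, and counts of features that shared a symbol were added. The uninjured matrix had 2174326 barcodes and 100935111 UMIs, the injured matrix 2601105 barcodes and 109420575 UMIs. Barcodes with at least 500 UMIs numbered 66551 and 38463.

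Cells were called as barcodes with at least 500 UMIs, at least 200 genes and at most 30% of UMIs from features of the mitochondrial genome. The first pair of limits left 17161 and 14536 barcodes and the mitochondrial limit 7073 and 9351. Doublets were scored with Scrublet in scanpy, whose automatic threshold marked 6.02% of the uninjured and 0% of the injured cells and so did not work in the injured library. The cells with the highest scores were therefore removed at a rate of 0.8% per 1000 cells called, which took 400 and 700 cells. The cells kept held 30.1% and 53.0% of the UMIs of their library.

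Cells of both libraries were clustered together. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and a graph of 15 neighbours on 30 principal components was clustered with the Leiden method at resolution 1.0 and seed 0, without integration. Clusters were named from 15 marker lists fixed before the data were examined. A cluster took the name of the list with the highest mean log2 fold over the other cells if that mean reached 0.8, led the next list by 0.5 and at least 3 markers were detected in 10% of its cells and 2 times as high as elsewhere, unless its 10 leading genes held more markers of another class or at least 3 cell cycle genes, or the cluster had few UMIs and none of its own markers among them. The thresholds of this rule, not the markers, were set after the data were seen. No cluster met it for T cells, neural or Schwann cells or epithelial cells. Names are given as X-like, and they rest on these rebuilt clusters and not on an annotation by the authors.

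For each class with at least 50 cells in both libraries (8 classes), raw UMIs were summed per library and divided by the class total to give counts on a common scale (CPM). With 1 library per group there was no test, and cells were not used as replicates. Summed counts have exact Poisson intervals, ratios of counts exact conditional binomial intervals, and shares of cells exact binomial (Clopper-Pearson) intervals, all at 95% and all covering counting error only. UMIs of 1 cell are not independent, so these intervals are too narrow even for the cells of 1 library. Log2 ratios (injured over uninjured) used a pseudocount of 5 CPM, whereas folds used none. A fold against a count of 0 is given as a lower limit with 3 counts in place of 0. Genes were measured with at least 20 UMIs over both libraries in the class.

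The text names genes by a rule of size. In each class with at least 100 cells in both libraries (6 classes), these were the 8 highest and the 6 lowest log2 ratios among genes with at least 100 CPM and 50 UMIs in the library where they were higher and a level there no lower than in the free RNA of that library. The ratio interval had to exclude 2-fold, and mitochondrial, haemoglobin and ribosomal protein genes, markers of other classes and clone-based names were left out. From each gene list up to 4 measured members with the largest ratios could be named, and any member of the heparan sulphate pathway. sulf1, sulf2a and sulf2b were always reported, and genes that lead a cluster are named with it. No erythrocyte-like gene met the rule.

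The 14 gene lists, also fixed beforehand, covered the cell cycle (32 genes), extracellular matrix and remodelling (43), inflammatory cytokines and response (40), interferon response (27), the heparan sulphate pathway (46), heparin-binding growth factors and receptors (71), the sarcomere (35), cardiomyocyte stress and immature state (30), glycolysis (31), nuclear genes of oxidative phosphorylation (51), immediate early and AP-1 genes (29), heat shock and dissociation stress (22), lysosome and lipid handling (35) and endothelial activation and angiogenesis (35). For each, the median log2 ratio of at least 5 measured members was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, with an interval from 2000 bootstrap draws of the members. Members count as higher or lower at 1.5-fold on the log2 ratio, with its pseudocount of 5 CPM. The shares of all measured genes were counted alike, so scarce genes with a larger fold can go uncounted. Members of a list are not independent, so percentiles describe these libraries and are not p-values.

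Free RNA was taken from barcodes with 1 to 50 UMIs. Barcodes with at least 300 UMIs and under 200 genes are called empty droplets here. They numbered 52765 and 51429, and 89.2% and 84.1% of their UMIs were mitochondrial. The share of free RNA in cells, from haemoglobin genes outside erythrocyte-like cells, came to 6.47% in the uninjured and 1.23% in the injured library.

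The procedure was tested on simulated Poisson counts drawn at the depth of both libraries from the pooled gene shares of a class, with 200 genes changed. Intervals held the true ratio for 96.3% of unchanged and 94.2% of changed genes at the depth of fibroblast-like cells, and the direction was right, with an interval that excluded no change, for 75.0% of genes changed 2-fold and 98.9% of those changed 4-fold. Of 500 random lists of 30 genes, 6.20% fell outside the central 95% at that depth and 5.20% at the depth of cardiomyocyte-like cells. Because the draws were independent Poisson counts, coverage near 95% follows largely by construction. Dependence of UMIs within a cell and of genes on each other, and differences between libraries, were not simulated.

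Alternatives fixed in advance were a minimum of 1000 UMIs, a minimum set from the highest UMI counts, no mitochondrial limit or one of 15%, doublets kept, resolutions of 0.5 and 1.5, each library clustered alone, median-of-ratios scaling, totals without mitochondrial, haemoglobin and ribosomal protein genes, means of per-cell CPM, free RNA subtracted, no filter on low counts and pseudocounts of 1 and 20 CPM. A further 6 were chosen after seeing the data. They were 500 nuclear UMIs without a mitochondrial limit, mitochondrial genes recognised by prefix alone, unnamed clusters given to their best marker list, shares without erythrocyte-like and thrombocyte-like cells, clusters with under 2% of their cells from 1 library left out, and clusters of low UMI count left out.

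Shares of cells with a UMI of a gene were not compared, because depth differed between the libraries. Analyses used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.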

Results

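Single-cell RNA sequencing was carried out on dissociated heart ventricles of adult zebrafish that were homozygous for the sjr9 allele of sulf1. This gene encodes an extracellular endosulfatase that removes 6-O-sulphate groups from heparan sulphate, the glycosaminoglycan that binds many growth factors and chemokines. The zebrafish heart regenerates after injury, and the series was titled as a study of the role of Sulf1 in that process. There were 2 groups with 1 library each, uninjured ventricles and ventricles taken 4 days after cryoinjury, a freezing injury to the ventricle wall. The fish were 3 months old, and the uninjured library was a pool of 4 ventricles. The uninjured library held 100935111 unique molecular identifiers (UMIs) and the injured library 109420575. After cell calling and doublet removal, 6673 uninjured and 8651 injured cells were kept, with medians of 3914 and 5100.0 UMIs and of 943 and 1004 genes per cell. Mitochondrial transcripts made up a median of 19.8% of the UMIs of an uninjured cell and 12.8% of those of an injured cell.

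With 1 library per group there were no replicates, so no difference was tested against the spread between animals. Intervals are 95% and cover counting error only. Values are described as higher or lower in the injured library than in the uninjured library, and a difference between the animals, the dissociations or the library preparations cannot be told apart from the injury. Both libraries carried the mutation and wild-type hearts were not analysed here. The comparison therefore describes injured against uninjured mutant ventricles, not the effect of the mutation, and the sulf1 transcript level does not check the genotype.

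The first question was where the mutated gene and its relatives were transcribed. sulf1 transcripts were concentrated in fibroblast-like cells, which held 90.5% of the sulf1 UMIs of the uninjured cells and 92.6% of those of the injured cells. The fibroblast-like level was 184 CPM (UMIs scaled to the class total; interval 172 to 198) in the uninjured and 138 (130 to 147) in the injured library, a fold of 0.749 (0.681 to 0.824). sulf2b, which encodes a second sulfatase of the same family, was 6.33 times as high in the injured fibroblast-like cells (5.26 to 7.68), at 188 against 29.6 CPM. sulf2a was close to absent from both libraries, with 13 and 26 UMIs in all cells together, or 0.428 and 0.449 CPM.

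The fibroblast-like class was made of 2 clusters, and sulf1 differed between them. Cluster 5 held all 953 uninjured and 556 of the injured fibroblast-like cells, and sulf1 was among the leading genes of this cluster. Within it sulf1 was higher in the injured library, 259 against 184 CPM, a fold of 1.403 (1.27 to 1.55), so that leaving out the other cluster turned the direction of the class value. Cluster 23 held 284 injured and 0 uninjured cells, and its sulf1 level was 55.7 CPM (48.8 to 63.1). The levels of sulf2b ran the other way, 256 CPM (241 to 272) in cluster 23 and 87.1 CPM in the injured cells of cluster 5. Within cluster 5 alone sulf2b was still higher in the injured library, with a fold of 2.94 (2.36 to 3.67).

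Outside the fibroblast-like class sulf1 was scarce. In epicardial-like cells it was 9.33 CPM uninjured and 4.096 CPM injured (fold 0.439; 0.223 to 0.836), against 8.46 and 6.80 CPM in the free RNA of barcodes with 1 to 50 UMIs. Endothelial or endocardial-like, cardiomyocyte-like and macrophage-like cells all had less sulf1 than the free RNA of their own library. Mural-like cells had 29.4 CPM (10.8 to 64.0) uninjured and 14.3 CPM (1.74 to 51.8) injured, from 6 and 2 UMIs. In the injured neutrophil-like cells 16 sulf1 UMIs came from 1 cell. sulf2b was found more widely. It was 1.60 times as high in the injured endothelial or endocardial-like cells (1.39 to 1.84), at 73.0 against 45.5 CPM, and 6.24 times as high in the injured epicardial-like cells (3.86 to 10.7), at 38.1 against 6.11 CPM. The unnamed cluster 10, almost all of it from the injured library, held 35.3% of the sulf2b UMIs of the injured cells, at 86.2 CPM, against 39.2% in fibroblast-like and 11.095% in endothelial or endocardial-like cells. Free RNA held 6.52 CPM of sulf2b in the uninjured and 29.1 CPM in the injured library. Macrophage-like cells, with 32.9 and 25.01 CPM, showed no sulf2b difference that was detectable at this depth (fold 0.761; 0.559 to 1.06).

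**Figure D1:**
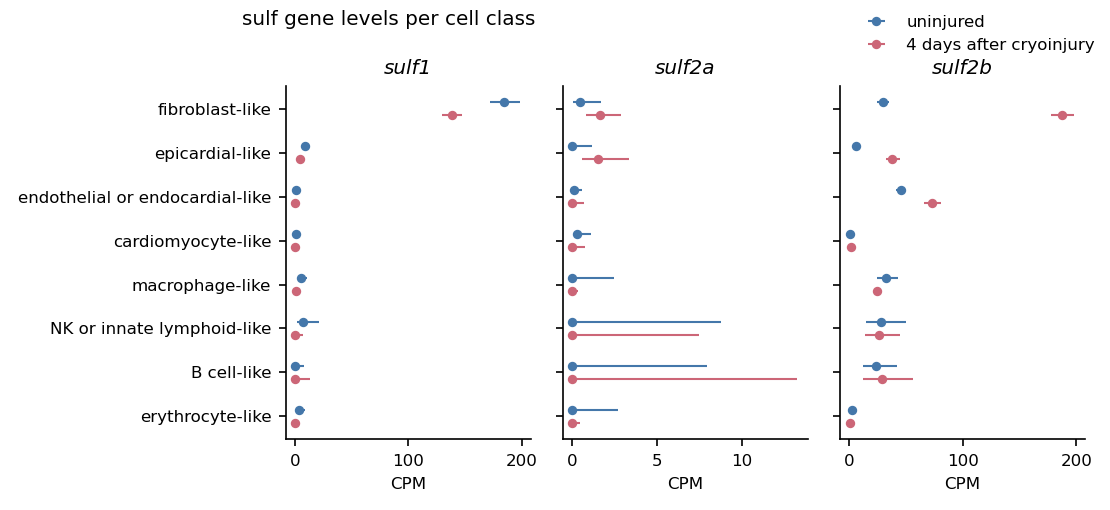
Levels of sulf1, sulf2a and sulf2b in CPM (x axis, a separate scale in each panel) in each cell class (y axis) of the uninjured (blue) and injured (red) library, with 1 library each and bars showing 95% exact Poisson intervals of the counts. sulf1 sits in the fibroblast-like class, at 184 and 138 CPM, whereas sulf2b is highest in the injured fibroblast-like class, at 188.

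The next question was which cell classes made up the cells recovered from injured and uninjured mutant ventricles. Macrophage-like cells, the phagocytes of the tissue, were 3.57% (3.13 to 4.04) of the uninjured and 13.6% (12.9 to 14.4) of the injured cells, a ratio of 3.82 (3.32 to 4.41). Thrombocyte-like cells, the nucleated counterparts of platelets, were 0.540% and 6.73%, a ratio of 12.5 (8.90 to 18.0). Neutrophil-like cells were 0.225% and 1.03%, a ratio of 4.58 (2.63 to 8.52). Endothelial or endocardial-like cells, which line vessels and the heart lumen, were 35.0% (33.9 to 36.2) of the uninjured and 13.4% (12.7 to 14.1) of the injured cells, a ratio of 0.382 (0.355 to 0.410). B cell-like cells were 1.87% and 0.890%, a ratio of 0.475 (0.353 to 0.636). These 5 directions were the same under every other processing setting that gave a value, although the ratios moved by more than 1.5 times under some: macrophage-like up to 6.75, thrombocyte-like down to 2.32, neutrophil-like down to 2.23 and endothelial or endocardial-like up to 0.702. The limit of 30% mitochondrial UMIs left 7073 of 17161 uninjured and 9351 of 14536 injured barcodes, and thrombocyte-like cells had a median of 3652 UMIs in the uninjured and 1473 in the injured library, near the minimum of 500. Shares add to a whole, so a larger share of one class lowers the shares of the others.

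Other shares depended on how cells were called or grouped. Cardiomyocyte-like cells were 26.4% (25.4 to 27.5) and 23.2% (22.3 to 24.1), a ratio of 0.878 that became 0.301 with cells called at a share of the highest UMI counts and 1.01 with erythrocyte-like and thrombocyte-like cells left out of the total. Their median depth was 3202 UMIs in the uninjured and 1859 in the injured library. Fibroblast-like cells were 14.3% (13.5 to 15.1) and 9.71% (9.09 to 10.4), a ratio of 0.680, and epicardial-like cells were 5.75% and 4.20%, a ratio of 0.729. The epicardial-like ratio became 1.27 with no mitochondrial limit, and the fibroblast-like ratio became 63.8 at a limit of 15%, where most uninjured fibroblast-like cells were lost or left without a name. Erythrocyte-like cells were 2.38% and 8.95%, a ratio of 3.75 that turned to 0.847 with no mitochondrial limit. NK or innate lymphoid-like (ratio 0.823; 0.611 to 1.11), dendritic-like (1.71; 0.970 to 3.10) and mural-like cells (0.621; 0.3803 to 1.01) showed no difference in share that was detectable at this depth.

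A further 7.67% of the uninjured and 16.3% of the injured cells lay in clusters that were left without a name, by thresholds of the naming rule that were set after the data were seen. Cluster 10 held 0.360% of the uninjured and 11.2% of the injured cells. Its leading genes included crlf1a, krt18a.1, nppc and postna, and it carried endothelial markers, but a mural marker stood among its leading genes and none of its own did. Because almost all of its cells came from 1 library, it may be a property of that library and not a cell type. Cluster 7 (6.98% and 3.21%) had too few detected markers of any class, and cluster 21 (0.330% and 1.88%) was led by cell cycle genes such as stmn1a, rrm2 and pcna. The best marker list of cluster 21 was that of cardiomyocytes, with a mean log2 fold of 0.919 and 8 markers over 2-fold. Giving each unnamed cluster to its best marker list raised the endothelial or endocardial-like ratio from 0.382 to 0.695.

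**Figure D2:**
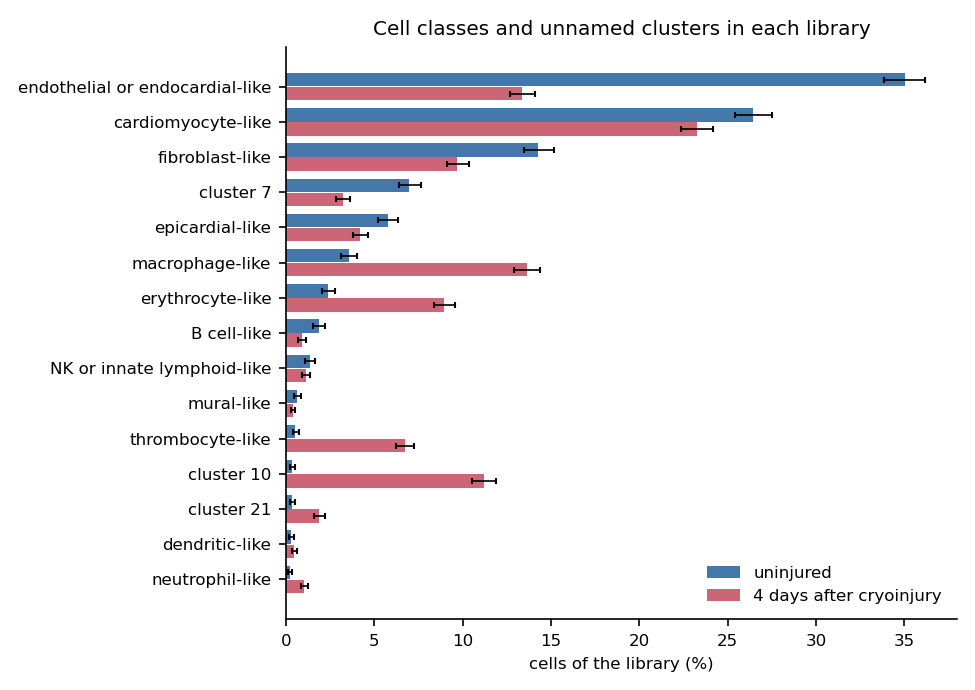
Share of the called cells (x axis, percent) in each cell class and unnamed cluster (y axis) of the uninjured (blue) and injured (red) library, 1 library each, with black lines showing exact binomial 95% intervals that cover counting error only. Macrophage-like cells are 3.57% of the uninjured and 13.6% of the injured cells, and endothelial or endocardial-like cells 35.0% and 13.4%.

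Gene levels were then compared within each class, to describe the injured and the uninjured state of the same kind of cell. Counts of list members at 1.5 times, taken from the log2 ratio with its pseudocount, can be read against all measured genes of the class. In cardiomyocyte-like cells 3.91% of these were at least 1.5 times higher in the injured library and 5.91% as much lower. The shares were 4.95% and 2.15% in endothelial or endocardial-like and 14.8% and 5.82% in fibroblast-like cells. In epicardial-like cells they were 19.6% and 7.93%, and in macrophage-like cells 17.9% and 5.94%. In cardiomyocyte-like cells, acta1a, which encodes the skeletal muscle actin, was 692 CPM in the injured and 112 CPM in the uninjured library, a fold of 6.20 (5.72 to 6.73). The myosin heavy chain gene myh7 was 5.24 times as high (4.43 to 6.23), and rcan1a, a regulator of calcineurin that is itself induced by calcineurin signalling, 4.28 times as high (3.71 to 4.95). The atrial myosin heavy chain gene myh6 was lower in the injured library, 20.9 against 149 CPM (fold 0.141; 0.113 to 0.173). So were pdk2b and pdk2a, which encode kinases that restrain pyruvate dehydrogenase, with log2 ratios of -2.28 and -1.21. The named genes of this class also included hspb12 (small heat shock protein; log2 ratio 1.17) and hmgn2 (nucleosome-binding protein; 1.72) on the higher side. On the lower side were smdt1b, a subunit of the mitochondrial calcium uniporter (-1.26), the kinase gene mylk4b (-1.24) and the titin gene ttn.2 (-1.14), one of the markers of the class. hmgn2 was about as abundant in free RNA, 136 and 398 CPM, as in the class, 129.9 and 439 CPM. The log2 ratio of myh6 (-2.57) turned to 0.49, higher in the injured library, at a mitochondrial limit of 15%, and with cells called at a share of the highest UMI counts those of ttn.2 and hmgn2 were -0.38 and 2.36.

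Of the 13 cell cycle genes measured in cardiomyocyte-like cells, 11 were at least 1.5 times as high in the injured library and 0 as much lower, with a median log2 ratio of 0.93 (bootstrap interval over members 0.77 to 1.16). Among them were stmn1a, a microtubule regulator (2.30), pcna, the sliding clamp of replication (12.2 and 51.3 CPM; 1.71), and gins2 of the replicative helicase (1.21). With doublets kept, stmn1a and pcna became 0.99 and 0.81. All were low in abundance, and the median depended on the pseudocount, 0.32 with 20 CPM, and became 0.16 without the filter on low counts. The class did not include the unnamed cluster 21, which scored best on the cardiomyocyte list but was left out because cell cycle genes led it. Of 28 measured genes of cardiomyocyte stress and the immature state, 6 were 1.5 times higher and 1 lower, with a median of 0.19. They included tagln, an actin-binding protein (2.16, and 1.51 to 3.77 under other settings), and ankrd1a, a stress-responsive sarcomere protein (2.03). Immediate early and AP-1 genes were mostly lower: 15 of 23 were 1.5 times lower and 1 higher, with a median of -0.75 (-0.86 to -0.26), among them egr1 (-1.52) and nr4a1 (-1.41). That median was -0.13 with no mitochondrial limit, and egr1 and nr4a1 were -0.82 and -0.76 with means of per-cell CPM, with egr1 at -3.07 at a mitochondrial limit of 15%.

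Nuclear genes of oxidative phosphorylation had a median of -0.12 in cardiomyocyte-like cells, with 6 of 48 at least 1.5 times lower (ndufa1 of complex I, -0.94; uqcrb of complex III, -0.94) and 1 higher, a sign that turned under some settings (0.05 with no mitochondrial limit). Of 28 sarcomere genes 2 were 1.5 times higher and 6 lower (median -0.10, 6.95th percentile of random lists). Extracellular matrix genes had a median of 0.53, with 8 of 19 higher, but the median was -0.22 with doublets kept. Inflammatory genes had a median of 0.36, with 5 of 16 higher, led by the cytokine signalling inhibitor socs3b (1.95), and an interval that included 0, and that median was -0.75 at a mitochondrial limit of 15%. Different clusters held most of the class in the 2 libraries. Cluster 6 held 1033 of the 1765 uninjured cells, and clusters 4 and 8 held 732 and 767 of the 2010 injured cells. acta1a and hspb12 were among the leading genes of clusters 4 and 8, so that their class values move with these clusters. The median over all 7321 genes measured in the class was -0.03.

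In endothelial or endocardial-like cells, gpd1b, which encodes a glycerol-3-phosphate dehydrogenase, was seen with 532 UMIs in the injured and 12 in the uninjured library, or 100.3 against 1.26 CPM, a fold of 79.7 (45.3 to 155). It was higher in the injured cells of all 5 clusters of the class, with 125 against 1.79 CPM in cluster 1, which held the largest part of the class in both libraries, and with overlapping intervals in cluster 16 (8.03 against 2.25 CPM). jdp2b, which encodes an AP-1 family repressor, was 4.09 times as high (3.79 to 4.41), and tfpia, an inhibitor of the tissue factor pathway of coagulation, 2.81 times as high (2.59 to 3.04). Other genes on the higher side were cd99 (adhesion molecule; log2 ratio 1.28), the gap junction gene cx43 (1.23), the tight junction gene cldn5b (1.23), fosb (1.17) and the interferon-inducible gene ifitm1 (1.16). At a mitochondrial limit of 15% the log2 ratios of jdp2b (1.98), cldn5b and fosb were 1.16, 0.33 and 0.42, and with the unnamed cluster 10 in the class those of cldn5b, ifitm1 and tfpia (1.45) were 0.61, 0.42 and 2.30. No gene on the lower side met the rule for named genes. cldn5b was among the leading genes of cluster 16, which held 3.25% of the uninjured and 8.05% of the injured cells of the class. It was also a leading gene of the thrombocyte-like cluster, and free RNA held 6.87 CPM of it in the uninjured and 26.8 CPM in the injured library.

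The inflammatory list had a median of 0.45 (0.17 to 0.82) in endothelial or endocardial-like cells, with 10 of 23 measured genes at least 1.5 times higher and 0 lower. Examples were tnfaip2b, a gene induced by tumour necrosis factor (2.02), and ptgs2a, a prostaglandin synthase (1.21), which became 1.11 and 0.46 at a mitochondrial limit of 15% and 1.25 and 2.77 with the unnamed cluster 10 in the class. Extracellular matrix genes had a median of 0.30 (0.19 to 0.61), with 12 of 32 higher and 0 lower. They included timp2b, an inhibitor of matrix metalloproteinases (2.04). With the unnamed cluster 10 counted in the class, this median was 1.28, timp2b was 3.87, and col1a1a went from 0.94 to 3.62. Of 29 genes of endothelial activation and angiogenesis, 6 were higher and 1 lower (median 0.26, which turned to -0.23 with cluster 10 in the class and to -0.26 with each library clustered alone), among them plvapb, a component of fenestrae and a leading gene of cluster 16 (1.45). Of 46 heparin-binding growth factors and receptors, 9 were higher and 1 lower (median 0.19, 96.6th percentile). The highest was the chemokine gene cxcl12b, also a leading gene of cluster 16 (6.19 and 64.5 CPM; 2.63), followed by the receptor gene cxcr4b (1.09). Immediate early and AP-1 genes, with 5 of 26 higher and 0 lower, had a median of 0.44 (0.36 to 0.53). It turned to -0.26 at a mitochondrial limit of 15% and to -0.17 with cluster 10 in the class.

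The heparan sulphate pathway, the substrate of the mutated enzyme, did not stand out as a group. In endothelial or endocardial-like cells the 25 measured genes had a median of 0.11, at the 66.4th percentile of random lists, and sulf2b had the largest log2 ratio (0.63), followed by xylt1, the enzyme that starts the glycosaminoglycan chain (0.58, and 1.64 with cluster 10 in the class), and ext1a, a chain polymerase (0.51). In epicardial-like cells 7 of 26 were higher and 2 lower (median 0.30, 75.8th percentile), among them xylt1 (1.09) and the glypican gene gpc4 (0.93). In fibroblast-like cells 9 of 32 were higher and 4 lower (median 0.15, percentile 55.3). The highest was gpc1b, a glypican core protein (6.75 and 78.9 CPM; 2.84), before sulf2b (2.48), gpc4 (1.47) and the 2-O-sulphotransferase gene hs2st1b (1.45), whereas ndst2b, a deacetylase and sulphotransferase (-0.75), and gpc6a (-0.63) were lower. Without cluster 23 the values of gpc1b, gpc4 and hs2st1b were 0.71, 0.61 and 0.86. In macrophage-like cells 5 of 18 were higher and 1 lower (median 0.11, 24.7th percentile). Only 4 members could be measured in cardiomyocyte-like cells, too few for a median.

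In fibroblast-like cells, the ratios of most named genes were closer to 0 without cluster 23, which had no uninjured cells. postnb, the matricellular protein periostin, was 865 against 47.5 CPM, a log2 ratio of 4.05, and was 143 CPM in the injured cells of cluster 5 alone. Without cluster 23, the log2 ratio of the pentraxin gene ptx3a (5.16) became 1.4, that of the small proteoglycan gene lum (3.56) 2.41 and that of the globin family gene cygb1 (2.92) 0.65. The chaperone gene clu (3.01) became 2.07, the fibronectin gene fn1a (2.48) 0.95, and the collagen XII genes col12a1a (3.17) and col12a1b (2.49) became 0.97 and 1.1. The collagen gene col11a1b had 1074 UMIs in the injured and 0 in the uninjured cells, a level at least 204-fold higher with 3 counts in place of 0 (lower limit of the exact interval 165). This level was taken with cluster 23 included, and no level in cluster 5 alone is given for it. clu, fn1a, postnb, col11a1b and both collagen XII genes were among the leading genes of cluster 23, and lum and col12a1a were markers used to name the class. postnb was a marker of the epicardial list. Cluster 23 scored second on that list, with a mean log2 fold of 1.27 against 2.16 on the fibroblast list, so its cells also carried epicardial markers. On the lower side were fgl2a (fibrinogen-like protein; 112 and 20.0 CPM; -2.22), vmo1a (151 and 31.3 CPM), the complement factor gene cfd (-2.03), myoc (-1.66), the heat shock gene hsp70l (-1.64) and rasgef1ba (-1.61). Without cluster 23 these genes stayed lower, with log2 ratios of -1.36, -1.65, -1.002, -0.55, -1.03 and -0.77 in turn.

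Extracellular matrix genes had a median of 0.82 (0.41 to 1.01) in fibroblast-like cells, with 21 of 39 at least 1.5 times higher and 2 lower, and of 0.51 without cluster 23. The inflammatory list had a median of 0.63, with 14 of 26 higher and 1 lower, and examples were the cytokine gene il11a (2.61), ptgs2a (2.41) and the chemokine gene cxcl8a (10.1 and 59.7 CPM; 2.096), which became 1.503, 1.76 and 0.87 without cluster 23. Of 24 cell cycle genes 14 were higher, with a median of 0.66, led by the ribonucleotide reductase subunit rrm2 (2.40), but the median turned to -0.20 without cluster 23. Of 43 heparin-binding growth factors and receptors 8 were higher and 10 lower (median -0.12, 0.01th percentile of random lists, interval including 0). The related midkine genes went opposite ways, mdka 1891 and 6005 CPM (1.66) and mdkb 41.4 and 2.88 CPM (-2.56), and receptor tgfbr2a was higher (1.56). Lysosome and lipid genes had a median of 0.50 (0.29 to 1.13), with 11 of 25 higher, and the interferon list one of 0.44, with 7 of 17 higher. Heat shock genes were lower, with 10 of 22 at least 1.5 times lower and 1 higher (median -0.47, interval including 0). Immediate early genes, with 7 of 26 lower and 3 higher, had a median of -0.24. aldh1a2, the enzyme of retinoic acid synthesis, was 196 against 16.4 CPM (3.24) within an endothelial activation list whose median was -0.22. It was also a marker of the epicardial list.

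Epicardial-like cells, the outer lining of the heart, formed 1 cluster that held 384 uninjured and 363 injured cells. They split largely by library under some other settings, as with cells called at a share of the highest UMI counts, into clusters of 380 and 55 and of 3 and 313 uninjured and injured cells. clu was 523 against 33.4 CPM, a fold of 15.6 (12.8 to 19.2), and fn1a 262 against 16.7 CPM, a fold of 15.7 (11.9 to 21.2). The log2 ratio of clu (3.78) became 3.17 with 500 nuclear UMIs and no mitochondrial limit. Other genes on the higher side were the linker histone gene h1f0 (log2 ratio 3.14), the metalloreductase gene steap4 (3.07), the complement gene c7a (3.05), the claudin genes cldn5a (2.58) and cldnc (2.55) and mxra8a (a fold of 6.77). On the lower side were ptgdsb.1, a prostaglandin D synthase (356 and 26.4 CPM; -3.53), the chloride transporter gene clcn5b (-2.85), prx (-2.84), the matrix protease gene adamts9 (-2.75), slc5a8l (-2.51) and cxxc5a (-2.35). Of 35 extracellular matrix genes 24 were at least 1.5 times higher and 2 lower, with a median of 0.97 (0.69 to 1.28), among them the thrombospondin gene thbs1b (22.2 and 96.2 CPM). thbs1b was also a thrombocyte marker and a leading gene of the thrombocyte-like cluster, whose share was larger in the injured library. The matrix median kept its sign under every setting, between 0.68 and 1.11.

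Immediate early and AP-1 genes were also higher in epicardial-like cells, with 12 of 25 higher and 1 lower (median 0.58; 0.16 to 0.94), led by the phosphatase gene dusp2 (1.95) and btg2 (1.70). Of 23 inflammatory genes 11 were higher and 4 lower (median 0.44). cxcl8a was higher (1.47) and its relative cxcl8b.1 lower (-1.63). Of 15 interferon genes 7 were higher and 1 lower (median 0.46, 96.4th percentile), led by isg15 (2.18). Glycolysis genes had a median of -0.41 (-0.71 to -0.10), with 8 of 22 lower and 0 higher. Examples were aldoab (-1.01) and gapdh (-0.82), both more abundant in free RNA, which held 1728 and 1056 CPM of gapdh in the uninjured and injured library, than in the class, at 264 and 147 CPM. Of 38 heparin-binding factors and receptors 7 were higher and 5 lower (median -0.01, 1.98th percentile of random lists), with mdka again higher (1.71) and mdkb lower (-1.69).

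Macrophage-like cells were 1 cluster of 238 uninjured and 1178 injured cells, whose leading genes included the immune genes acod1, il1b and cxcl19. apoeb, an apolipoprotein E gene, had 1406 UMIs in the injured and 2 in the uninjured cells, or 138 against 1.34 CPM, a fold of 103 (28.4 to 850.0). fth1a, the ferritin heavy chain for iron storage, was 4.41 times as high in the injured library (4.21 to 4.62), and the acute-phase gene saa 10.7 times (7.25 to 16.3). The progranulin gene grn2, one of the markers used to name the class, was 9.24 times as high. glrx (glutaredoxin; log2 ratio 2.65), ephx2 (epoxide hydrolase; 2.33), the glycine transporter gene slc6a9 (1.98) and echdc2 (1.94) completed the higher side. The lower side held the chemokine genes ccl35.2 (133 and 28.3 CPM; -2.05) and ccl34b.1 (-1.76), nsa2 (-1.83) and the chaperone genes hsp70l (-2.04), bag3 (-1.84) and dnajb1b (-1.67). At a clustering resolution of 1.5 the log2 ratios of fth1a (2.14), slc6a9, nsa2 and ccl34b.1 were 3.21, 2.97, -2.501 and -2.67, and with doublets kept that of bag3 was -1.08.

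As groups, lysosome and lipid genes were higher in the injured macrophage-like cells, 13 of 28 by at least 1.5 times with 3 lower (median 0.45; 0.24 to 0.76). Examples were the proteases ctsd (1.21), lgmn (1.07), which also served as a marker, and ctsc (1.03). Nuclear genes of oxidative phosphorylation had a median of 0.53 (0.39 to 0.63), with 22 of 48 higher and 3 lower, among them sdha (1.67) and cox6a1 (1.35), while the muscle-type subunit cox7a1 was lower (-1.61, and -0.94 with free RNA subtracted). Of 26 cell cycle genes 12 were higher and 0 lower (median 0.54; 0.35 to 0.72), including the proliferation marker mki67 (1.55) and birc5a (1.18). Heat shock genes (11 of 22 lower, 0 higher; median -0.54) and immediate early genes (12 of 24 lower, 0 higher; median -0.55) were lower as groups, with fosab at -2.22 and egr1 at -1.44. The inflammatory list had a median of 0.00, with 5 of 37 higher and 7 lower. This lay at the 1.9th percentile of random lists, whose median was 0.19, so the list was low for this class. Extracellular matrix genes had a median of -1.06 with an interval that included 0, and it turned to 0.30 with no mitochondrial limit. The 2 groups of macrophage-like cells differed in number, and the uninjured total was 1491350 UMIs against 10194785.

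**Figure D3:**
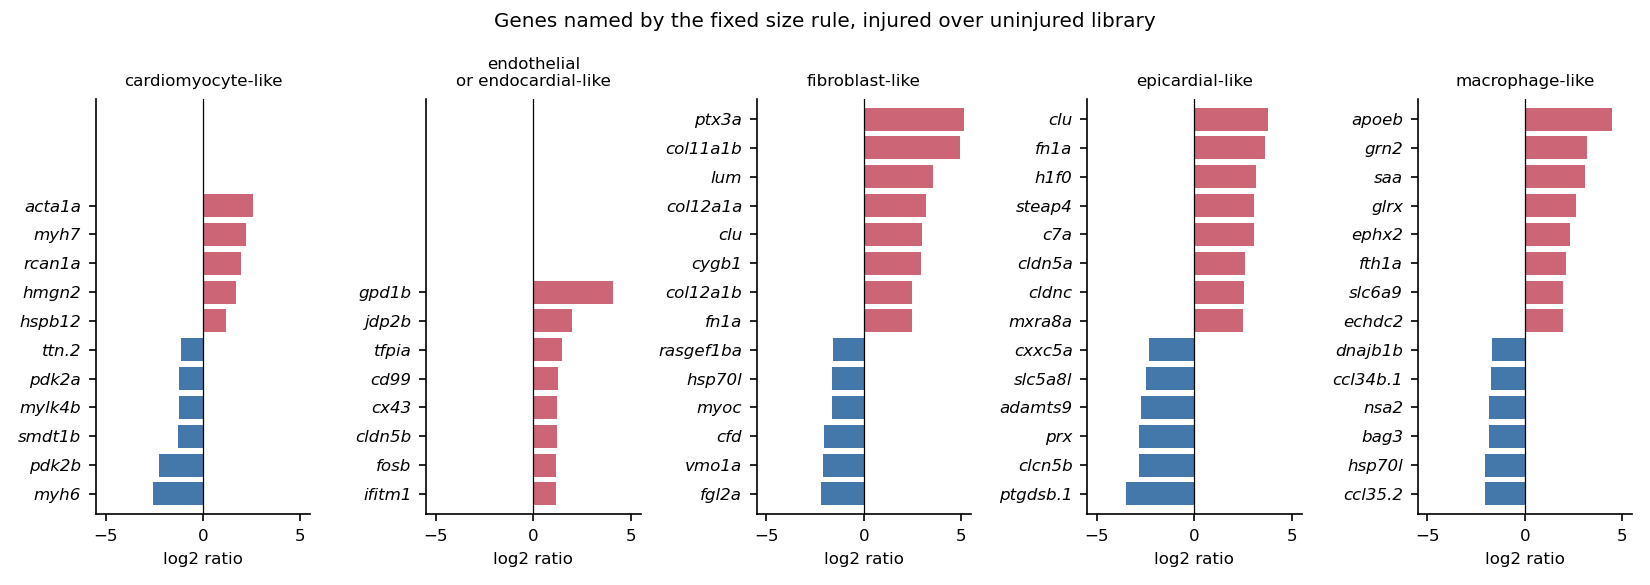
Log2 ratio of CPM, injured over uninjured library (x axis), of the named genes (y axis) of each cell class (panels), 1 bar per gene and 1 library per group, in red where higher and in blue where lower in the injured library. The largest values are ptx3a at 5.16 and col11a1b at 4.93 in fibroblast-like cells, and the lowest is ptgdsb.1 at -3.53 in epicardial-like cells.

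Sarcomere transcripts, the markers of cardiomyocytes, were lower in the injured library in the classes that should not make them. The median over the list was -0.66 in endothelial or endocardial-like, -1.31 in fibroblast-like, -0.80 in epicardial-like and -0.56 in macrophage-like cells. In the free RNA of barcodes with 1 to 50 UMIs these transcripts were 5.07% of the uninjured and 2.08% of the injured UMIs. Cardiomyocyte-type genes on other lists went with them. cox7a1 and cox5b2 were -1.98 and -1.16 in endothelial or endocardial-like cells, where oxidative phosphorylation had a median of -0.32, and pgam2 and aldoab were -1.57 and -1.76 in fibroblast-like cells, where glycolysis had a median of -0.20. Haemoglobin transcripts were 1.82% of the uninjured and 7.82% of the injured free RNA.

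Interferon response genes had medians of 0.12 in cardiomyocyte-like, 0.15 in endothelial or endocardial-like and 0.20 in macrophage-like cells. Glycolysis medians were 0.06 in endothelial or endocardial-like and 0.34 in macrophage-like cells. Oxidative phosphorylation had a median of -0.08 in fibroblast-like (0.66th percentile of random lists) and -0.05 in epicardial-like cells. Heat shock genes had a median of 0.31 in endothelial or endocardial-like cells, with 3 of 22 higher and 0 lower (hspb8, 0.95), and of -0.25 in epicardial-like cells. Lysosome and lipid genes had medians of 0.19 in endothelial or endocardial-like and 0.03 in epicardial-like cells. Genes of cardiomyocyte stress had medians between -0.22 and 0.02 in endothelial or endocardial-like, fibroblast-like, epicardial-like and macrophage-like cells, and cell cycle genes medians of 0.11 in endothelial or endocardial-like and 0.13 in epicardial-like cells. The heparin-binding list had a median of -0.05 in cardiomyocyte-like and -0.26 in macrophage-like cells. Endothelial activation genes had medians of 0.25 in epicardial-like and 0.31 in macrophage-like cells. The median over all measured genes was 0.09 in endothelial or endocardial-like, 0.14 in fibroblast-like, 0.20 in epicardial-like and 0.19 in macrophage-like cells.

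**Figure D4:**
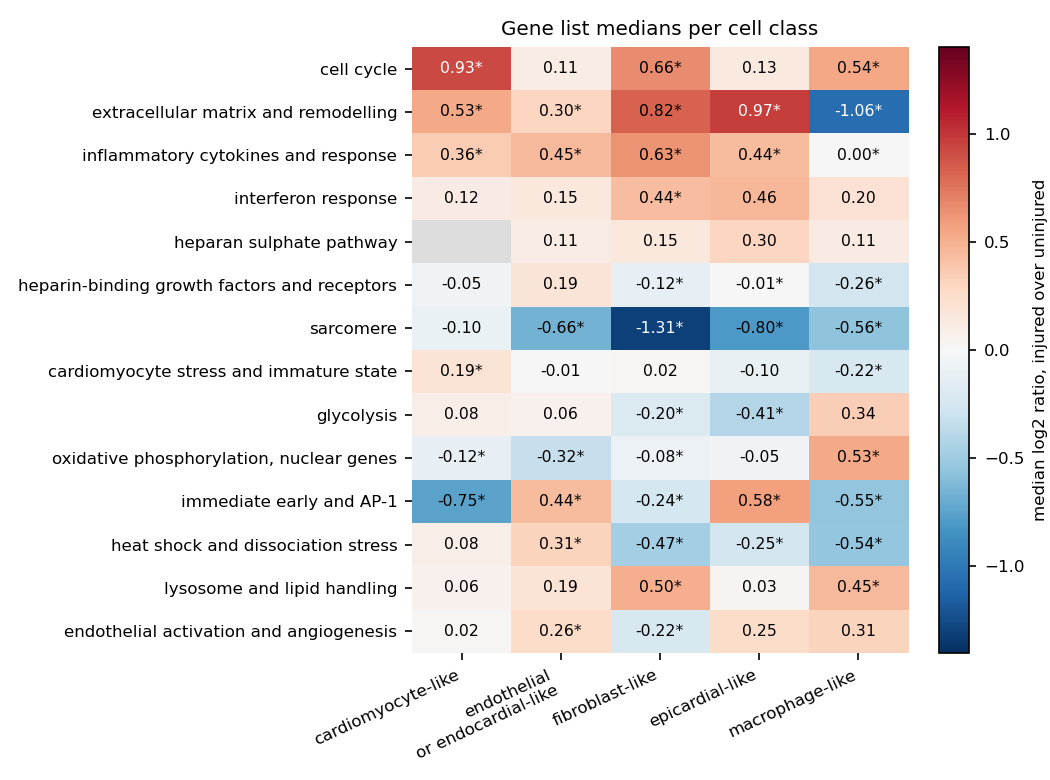
Median log2 ratio, injured over uninjured library, of each gene list (y axis) in each cell class (x axis) printed and coloured from blue (lower in the injured library) to red (higher), with 1 library each, asterisks outside the central 95% of matched random lists and grey for under 5 measured members. The sarcomere list is lower outside cardiomyocyte-like cells, with -1.31 in fibroblast-like cells.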

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

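The comparisons between cell classes given here were found by a search over all lists after the medians were seen, and none of the differences was tested. The search covered cardiomyocyte-like, endothelial or endocardial-like, epicardial-like, fibroblast-like and macrophage-like cells only. Other classes held lower medians, such as -1.18 for heat shock genes in NK or innate lymphoid-like cells. Haemoglobin transcripts in the empty droplets, barcodes that no cell class used, were 5.27 times as high in the injured library (4636 against 879 CPM), a signal outside the main measurement. The mitochondrial share of these droplets was 89.2% uninjured and 84.1% injured, so part of this fold comes from the totals. Nuclear genes of oxidative phosphorylation had a median log2 ratio of 0.53 in macrophage-like and -0.32 in endothelial or endocardial-like cells, opposite directions that differ by 0.86. The share of these genes in free RNA was 0.607 times as high in the injured library, and the endothelial or endocardial-like value includes cardiomyocyte-type members such as cox7a1 (-1.98). Immediate early and AP-1 genes had a median of 0.58 in epicardial-like and -0.75 in cardiomyocyte-like cells, a difference of 1.32. Heat shock and dissociation stress genes had a median of 0.31 in endothelial or endocardial-like and -0.54 in macrophage-like cells, a difference of 0.85.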

How the results depend on the processing

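Alternatives said to be added were chosen after seeing the data, and the cause of a change was not tested unless it is given. Reversed is said only of results whose main interval excluded no change (for medians, also outside the central 95% of random lists), so other values that changed sign are counted as moved or, if within the interval, as unmoved. No paired analysis was possible because each group had 1 library. Of 75 recomputed sulfatase folds 67 stayed within the interval of the main value, 7 moved beyond it and 1 reversed; of 127 ratios of shares these counts were 81, 38 and 8, of 352 medians of the lists followed in each class 291, 53 and 8, of 1000 other medians 887, 106 and 7, and of 1964 single-gene ratios 1574, 386 and 4. The folds of sulf2b stayed above 1 under every alternative for which they were recomputed (1.89 to 3.18 in all cells, 2.94 to 7.24 in fibroblast-like, 1.42 to 1.82 in endothelial or endocardial-like and 5.00 to 9.82 in epicardial-like cells). Sulfatase folds were not recomputed at other clustering resolutions or with the libraries clustered alone. They were also not recomputed with median-of-ratios scaling, means of per-cell CPM or free RNA subtracted. Share ratios stayed above 1 for macrophage-like (3.82 to 6.75), thrombocyte-like (2.32 to 16.6) and neutrophil-like cells (2.23 to 5.27), whereas those of endothelial or endocardial-like (0.393 to 0.702) and B cell-like cells (0.366 to 0.547) stayed below 1. Extracellular matrix medians stayed above 0 in epicardial-like (0.68 to 1.11) and fibroblast-like cells (0.51 to 0.89), as did the lysosome (0.17 to 0.56) and oxidative phosphorylation medians (0.26 to 0.76) of macrophage-like cells. Depth limits the rare classes and the genes of low abundance. At a mitochondrial limit of 15% fewer than 50 uninjured fibroblast-like or macrophage-like cells were left, so that their gene levels have no value there. No cluster was named B cell-like, dendritic-like, mural-like or neutrophil-like at that limit, and some other alternatives named no NK or innate lymphoid-like, dendritic-like or mural-like cluster, so these shares have no value.

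With cells called at 0.1 of the 99th percentile of UMI counts, share ratios were 0.301 for cardiomyocyte-like, 0.888 for fibroblast-like, 5.498 for erythrocyte-like, 5.78 for macrophage-like, 2.23 for neutrophil-like and 2.32 for thrombocyte-like cells, and that of epicardial-like cells reversed to 1.07. Cardiomyocyte-like medians were 1.404 for the cell cycle, -0.0301 for oxidative phosphorylation and 0.43 for stress genes, the cell cycle median was 0.88 in fibroblast-like cells, the immediate early median 0.55 in endothelial or endocardial-like cells, and the sulf1 fold 0.630 in fibroblast-like cells. With a minimum of 1000 UMIs the NK or innate lymphoid-like share ratio was 1.18.

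With no mitochondrial limit, the epicardial-like (1.27) and erythrocyte-like (0.847) share ratios reversed, and others were 0.758 for cardiomyocyte-like, 0.480 for endothelial or endocardial-like, 0.7585 for fibroblast-like, 5.71 for macrophage-like and 6.62 for thrombocyte-like cells. In cardiomyocyte-like cells the oxidative phosphorylation median reversed to 0.0514, and the cell cycle (0.72), immediate early (-0.13) and stress medians (0.42) moved. The immediate early median was 0.60 in endothelial or endocardial-like cells and the oxidative phosphorylation median 0.76 in macrophage-like cells.

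At a limit of 15%, share ratios were 0.469 for cardiomyocyte-like, 0.696 for endothelial or endocardial-like, 0.431 for epicardial-like, 2.14 for erythrocyte-like, 6.75 for macrophage-like and 2.76 for thrombocyte-like cells, and that of fibroblast-like cells reversed to 63.8. In endothelial or endocardial-like cells the medians of immediate early (-0.26) and endothelial activation genes (-0.0466) reversed, as did atf3 (-0.0422), dusp1 (-0.19) and egr3 (-0.32), and the matrix median was 0.18. In cardiomyocyte-like cells oxidative phosphorylation (0.0148), matrix (-1.05) and myh6 (0.49) reversed, and the immediate early median was -1.82. Folds over all cells were 0.8655 for sulf1 and 3.18 for sulf2b.

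With doublets kept, share ratios were 0.757 for cardiomyocyte-like, 0.438 for endothelial or endocardial-like and 2.98 for erythrocyte-like cells. Cardiomyocyte-like medians were 0.64 for the cell cycle, -1.05 for immediate early genes, -0.0327 for oxidative phosphorylation and, reversed, -0.22 for the matrix, and the macrophage-like oxidative phosphorylation median was 0.37. With the libraries clustered alone, ratios were 0.948 for cardiomyocyte-like and 0.702 for endothelial or endocardial-like cells. In the latter the matrix (1.39) and heparan sulphate medians (0.30) moved and the immediate early (-0.20) and activation medians (-0.26) reversed. A resolution of 0.5 gave a cardiomyocyte-like cell cycle median of 1.17, and one of 1.5 gave 0.63 and a macrophage-like share ratio of 4.93.

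With mitochondrial, haemoglobin and ribosomal protein genes left out of the total, medians were 1.26 (cell cycle) and -0.89 (immediate early) in cardiomyocyte-like and 0.16 (matrix) and 0.27 (immediate early) in endothelial or endocardial-like cells, and the fibroblast-like sulf1 fold was 0.666. Means of per-cell CPM gave cell cycle medians of 0.76 in cardiomyocyte-like and 0.28 in fibroblast-like cells and immediate early medians of 0.28 in endothelial or endocardial-like and -0.26 in cardiomyocyte-like cells. Without the filter on low counts, which adds genes near 0, the cardiomyocyte-like cell cycle median was 0.16 and the endothelial or endocardial-like inflammatory median 0.14. By their construction pseudocounts move ratios of scarce genes: cell cycle medians in cardiomyocyte-like, fibroblast-like and macrophage-like cells were 1.98, 1.17 and 1.13 with 1 CPM and 0.32, 0.28 and 0.19 with 20 CPM, and the cardiomyocyte-like immediate early median was -0.94 with 1 CPM. Median-of-ratios scaling, which sets the median gene to 0, gave 0.68 for the matrix in epicardial-like cells, 0.18 for the matrix and 0.30 for immediate early genes in endothelial or endocardial-like cells, -0.22, 0.26 and 0.17 for inflammatory, oxidative phosphorylation and lysosome genes in macrophage-like cells, and -0.0671 for oxidative phosphorylation in cardiomyocyte-like cells. With free RNA subtracted, sarcomere medians reversed to 0.31 in epicardial-like and 0.16 in macrophage-like cells, and the macrophage-like oxidative phosphorylation median was 0.71. The subtraction used 1 share per library, 6.47% uninjured and 1.23% injured. Haemoglobin was 0.0247% and 0.0234% of the UMIs of uninjured epicardial-like and macrophage-like cells, against 0.118% outside erythrocyte-like cells as a whole. More was therefore subtracted from these uninjured cells than their own haemoglobin would give, so the reversals may come from the subtraction itself.

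Of the added alternatives, 500 nuclear UMIs with no mitochondrial limit gave share ratios of 0.7255 for cardiomyocyte-like, 0.469 for endothelial or endocardial-like, 1.34 (reversed) for epicardial-like, 1.47 for erythrocyte-like, 5.36 for macrophage-like and 6.69 for thrombocyte-like cells, and medians of 0.56 for immediate early genes in endothelial or endocardial-like cells and of 0.67 and 0.0282 (reversed) for oxidative phosphorylation in macrophage-like and cardiomyocyte-like cells. Mitochondrial genes taken by prefix gave 0.821, 0.447, 1.21 (reversed), 0.938 (reversed), 5.48 and 6.755 for the same share ratios in turn and 0.761 for fibroblast-like cells, medians of 0.60, 0.74 and 0.0101 (reversed) in the same order, and 0.42 for cardiomyocyte-like stress genes. Unnamed clusters given to their best list made the ratios 0.938 for cardiomyocyte-like and 0.695 for endothelial or endocardial-like cells, the medians of the latter 1.28 (matrix), 0.30 (heparan sulphate), -0.17 (immediate early, reversed) and -0.23 (activation, reversed). By construction these changes come from cluster 21, which joined the cardiomyocyte-like class, and cluster 10, which joined the endothelial or endocardial-like class. Shares without erythrocyte-like and thrombocyte-like cells gave ratios of 1.01 (reversed) for cardiomyocyte-like, 0.439 for endothelial or endocardial-like and 0.783 for fibroblast-like cells. Without clusters that had under 2% of their cells from 1 library, the fibroblast-like cell cycle median (-0.20) and sulf1 fold (1.403) reversed, the sulf2b fold was 2.94 there, and folds over all cells were 0.564 for sulf1 and 1.89 for sulf2b. Without clusters of low UMI count the cardiomyocyte-like oxidative phosphorylation median was -0.0546.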

Other observations

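All tests of explanations given here were chosen after the pattern was seen, and only the prediction for cardiomyocyte doublets was written before its own result. In NK or innate lymphoid-like cells, 10 of the 13 measured cell cycle genes were at least 1.5 times as high in the injured library and 0 as much lower, with a median log2 ratio of 1.78 (0.67 to 1.91). The kinetochore gene cenpf had 0 CPM in the uninjured and 50.9 CPM in the injured cells, the mitotic kinase gene plk1 2.38 and 48.8 CPM, and the spindle gene tpx2 4.75 and 50.9 CPM. Free RNA of the injured library held only 1.13, 2.52 and 2.02 CPM of these genes. The class was small, with 90 uninjured and 96 injured cells. Its heat shock genes were lower, 15 of 21 with 1 higher (median -1.18), as were its immediate early genes, 19 of 24 with 0 higher (median -0.81), and the cytokine gene tnfa, 87.9 CPM in the uninjured and 8.14 CPM in the injured cells. Haemoglobin transcripts of this class were 26.1 times as high in the injured library, against 4.29 times in free RNA, so transcripts of another cell type differed along with the cell cycle genes.

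B cell-like cells, with 125 uninjured and 77 injured cells, had lower immediate early genes as well, 11 of 21 with 1 higher (median -0.75), and 9 of 18 heat shock genes were lower with 0 higher (median -0.42, interval including 0), such as hspb1 (995 and 100.6 CPM). The sarcomere list, whose transcripts come from cardiomyocytes, had a median of -2.12 in this class. The chemokine receptor gene cxcr4a was 255 CPM in the uninjured and 650.3 CPM in the injured B cell-like cells, against 8.99 and 6.55 CPM in free RNA. Over all cells together, the itaconate enzyme gene acod1 was 123 CPM in the uninjured and 838 CPM in the injured library, and the heparanase gene hpse, whose product cleaves heparan sulphate chains, 3.53 and 15.6 CPM, values that also reflect which classes were recovered.

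Cluster 10, with 24 uninjured and 970 injured cells, held the endothelial transcripts cdh5 (782 CPM), fli1a (233) and tie1 (197) together with those of the fibrillar collagen col1a1a, 2262 CPM against 260.0 in the injured endothelial or endocardial-like class. In that class cdh5, fli1a and tie1 were lower than in the cluster, at 638, 164 and 102 CPM. The endothelial gene kdrl went the other way, with 97.6 CPM in the cluster and 168 in that class. Doublets of an endothelial and a fibroblast-like cell were argued against, because fibroblast markers other than collagens reached a median of only 0.188 of the level that such doublets would need, with values against either fibroblast-like cluster between 0.00328 for mfap5 and 0.440 for pdgfra. The injured cells of the cluster had a median of 12310.5 UMIs, against 3755.5 in the injured endothelial or endocardial-like class, which was not explained. Free RNA from fibroblasts was argued against, because the collagen I genes were at least 3.69 times as high in the cluster as in the free RNA. Since 97.6% of the cells of the cluster came from the injured library, a property of that library other than the injury could not be told apart from it. No biological explanation of this pattern was tested.

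Sarcomere transcripts were lower in the injured library in 6 classes that should lack them. Less free cardiomyocyte RNA in the injured library may account for part of this, since the sarcomere share of free RNA was 0.411 times that of the uninjured library. The ratios in the 6 classes lay between 0.244 and 0.509. The genes of the list were ranked much as in free RNA in every class (lowest rho across genes 0.854, where genes are not independent replicates). Doublets with cardiomyocytes could give a like order, so the rank order does not tell these explanations apart. The injured levels were at least 1875 CPM, where free RNA held 20826 CPM. They are above what the 1.23% of free RNA estimated from haemoglobin genes would bring. How much free RNA the cells carry therefore stays open. In the empty droplets the sarcomere share was 1.17 times that of the uninjured library. This value cannot decide the question. The mitochondrial share of these droplets was 89.2% uninjured and 84.1% injured, which by itself raises all other shares in the injured library. Cardiomyocyte doublets among the uninjured cells were argued against, because at least 62.3% of the sarcomere level of each class was left without the 5% of cells that had the highest share. No biological explanation was tested.

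sulf1 was lower in the injured fibroblast-like class as a whole (0.749). A different mix of the 2 fibroblast-like clusters might account for this, since sulf1 was 1.403 times as high in the injured cells of cluster 5 alone, and cluster 23, found only in the injured library, had a low level. As sulf1 was among the leading genes of cluster 5, the clustering itself could have sorted cells by it. With mitochondrial, haemoglobin and ribosomal protein genes left out of the total, the fold was 0.666. This was no test of the lower mitochondrial share of the injured class (9.81% against 19.2%). A lower share raises the CPM of all other genes together, so the direction of the change was fixed by the totals. Whether the cells of cluster 23 derive from cells like those of cluster 5 was not tested.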
